A study of Mus musculus with 2 samples.

How the data were processed

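H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was profiled by ChIP-seq in cells sorted from mouse hearts at embryonic day 10.5. There were 2 libraries. The first came from EGFP-positive cells labelled as atrioventricular canal (AVC), the second from Katushka-positive cells labelled as chambers. Both carried the same strain and genotype labels, and each tissue had 1 sample.

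Per the labels' protocols, sorted cells were fixed, chromatin was immunoprecipitated with an H3K27ac antibody, and libraries were sequenced on a SOLiD instrument. The submitters' processing notes name Bowtie, SAMtools and the mm9 build, without versions or roles. Peaks on chromosome 1 reached position 197068273 in the chamber list. Per the file headers, peaks were called separately for each library with OccuPeak 1.3, chromosome by chromosome, with a Log(ER) threshold of 2, a read length of 50 and a modelled fragment length of 60.5 bp (AVC) or 68 bp (chambers). Whether a control library was used, and whether material was pooled before sequencing, is not given in the sources used here.

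Each deposited list gives a position and 2 numbers per peak. The score deposited by the authors is the caller's Log(ER), whose log base the header does not state; all deposited scores exceed 2. The other is a whole-number signal value that the file headers do not name, either the reads of a peak or the height of its pile-up, deposited without scaling between lists. Within a chromosome every signal value had a single score, and across a list the Spearman correlation of value and score was 0.975 (AVC) and 0.991 (chambers), and within chromosomes the score rose with the value except for 27 AVC and 20 chamber peaks, the highest 1 or 2 values of a chromosome, which scored below a smaller value. The scores on the mitochondrial chromosome were the same 6 numbers in both lists although the signal values differed. Scores and values mainly served to rank or filter peaks within a list; counts at equal scores and ratios of values between the lists are unscaled descriptions. Sequencing depth is unknown. The signal values summed to 5094191 (AVC) and 3363942 (chambers), which is not the depth of the libraries.

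A peak was shared when at least 1 bp overlapped a peak of the other list, counted with interval searches whose counts were checked against bedtools 2.31.1. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Chance overlap was the mean over 100 circular shifts of a list, each chromosome by a random offset. With 1 library per tissue no test between tissues was made, and no SD or p-value is given. A peak missing from a list was not called there, which does not show that acetylation was absent.

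Regional differences were counted in 100 kb windows with at least 20 peaks over both lists, mitochondrial peaks left out, each peak placed by its midpoint. The AVC share of the peaks in a window was compared with the pooled share over these windows. A window whose 95% interval lay above or below that baseline was called AVC-rich or chamber-rich; peaks of 1 window are not independent, so the interval is too narrow. The same windows were filled 100 times by binomial draws at the baseline share. A simulation drew peaks independently in the 1304 real windows, without the dependence between peaks of a window. Of 100 windows planted at an AVC share of 80%, 86.0% were recovered, and of 100 planted at 20%, 88.0%. Of 1104 windows at the baseline, 3.17% were set apart. As a check of the counting only, 20000 peaks cut out of the 87572 AVC peaks were all found to overlap them.

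The overlap definition, 5 of its 7 alternatives and the naming of peaks were fixed before the data were examined; the limit to peaks of at least 300 bp and the ranking by signal value were added afterwards. The peaks named are the 5 of highest score in each list and the 5 of highest score among peaks without overlap. The windows, the split by width and their alternatives were chosen after the lists had been seen. The windows named are the 10 with the highest lower bound of the AVC share, the 10 with the lowest upper bound (the window from 104.3 Mb on chromosome 2, with 4 AVC and 16 chamber peaks, tied with the last and is not named among them), and the 5 with the most peaks of at least 300 bp in the poorer list. The planned counts of marked promoters, the 16 gene lists and the 17 sequence motifs were not run, because no mm9 annotation or sequence was used here; the gene table at hand is for GRCm38, and coordinates were not converted. It served only for the number of protein-coding genes per chromosome. Positions are mm9, 1-based. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.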

Results

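H3K27ac peak lists were compared between the atrioventricular canal, the segment between atria and ventricles from which the atrioventricular node and the valve cushions form, and the heart chambers, the atria and ventricles. The series title gives its subject as the epigenome of separate cell types of the developing heart, and the comparison asks which H3K27ac regions the canal and the chambers share. The AVC list held 87572 peaks covering 42.4 Mb of the mm9 genome, and the chamber list held 67092 peaks covering 23.6 Mb. AVC peaks had a median width of 472 bp (interquartile range 388 to 567) and chamber peaks of 325 bp (248 to 421). Each tissue was represented by 1 library, so none of the differences below has a replicate check, and intervals cover counting error only.

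Most called peaks belonged to a single list. In the AVC 20324 peaks overlapped a chamber peak (23.2%, 95% interval 22.9 to 23.5) and 67248 did not. In the chambers 21226 peaks overlapped an AVC peak (31.6%, 31.3 to 32.0) and 45866 did not. Chance overlap was far lower, at 2.10% for AVC peaks (range over 100 shifts 1.89 to 2.27) and 2.86% for chamber peaks (2.62 to 3.19). The bases covered in both lists came to 6.30 Mb, which was 14.9% of the AVC territory and 26.7% of the chamber territory. With a neighbour within 1 kb counted as shared, the chamber share was 47.5% and the AVC share 32.9%.

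Sharing went with peak strength in both tissues. Of the weakest AVC peaks, with scores from 2 to 2.5, 11.8% (11.5 to 12.1) overlapped a chamber peak, against 62.4% (61.1 to 63.7) of those with scores from 5 to 10 and 98.1% (97.55 to 98.53) of those at 10 or more. The chamber peaks went from 16.8% (16.3 to 17.2) over 59.0% (57.9 to 60.1) to 92.1% (91.2 to 92.8) across the same classes. Width changed along with strength. In the top class 2057 of 3188 AVC and 1819 of 4333 chamber peaks were under 300 bp wide, and nearly all of these were shared. Among its peaks of at least 500 bp, 92.1% (AVC) and 85.4% (chambers) were shared. Peaks at a score of 5 or more that lay in a single list numbered 2141 in the AVC, out of 8716, and 3543 in the chambers, out of 12137.

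**Figure D1:**
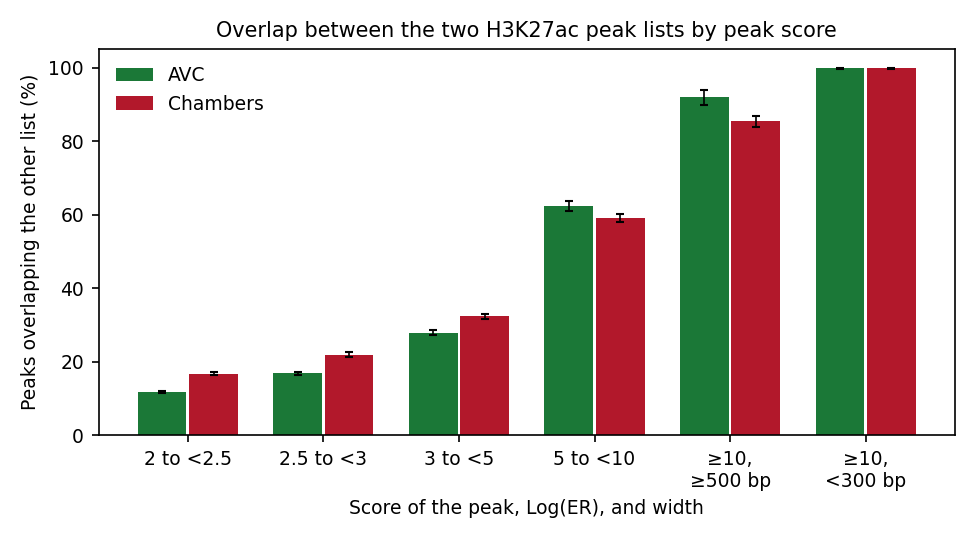
Percentage of peaks overlapping the other list by at least 1 bp, by score class and, at scores of 10 or more, by width; bars are AVC (green) and chambers (red), and error bars are exact 95% binomial intervals for counting error. Overlap is 11.8% for the weakest AVC peaks and over 99% for strong peaks narrower than 300 bp in both lists.

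Peaks with a score of 10 or more were mostly narrow or broad; 348 in the chambers and 407 in the AVC had widths between these classes. Strong broad peaks, with a score of 10 or more and a width of at least 500 bp, numbered 2166 in the chamber list (3.23% of its peaks) and 724 in the AVC list (0.827%). Of these, 85.4% (83.9 to 86.9) of the chamber peaks and 92.1% (89.9 to 94.0) of the AVC peaks were shared. Strong narrow peaks, under 300 bp wide, numbered 1819 in the chambers and 2057 in the AVC, with median widths of 162 and 161 bp, and 1818 and 2054 of them were shared. Broad peaks made up 49.99% (48.5 to 51.5) of the chamber peaks and 22.7% (21.3 to 24.2) of the AVC peaks at a score of 10 or more. At a score of 5 or more there were 5844 in the chambers, 48.2% (47.3 to 49.0), and 5163 in the AVC, 59.2% (58.2 to 60.3), so which list had the larger broad share depended on the threshold. Scores are set within each chromosome of a list, and equal scores in both lists need not mark equal enrichment. The AVC-to-chamber ratio of the unscaled signal value depended on the list from which strong broad peaks were taken: its median was 1.62 over the broad peaks of the AVC list and 0.491 over those of the chamber list, against 1.71 over the strong narrow peaks of either.

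**Figure D2:**
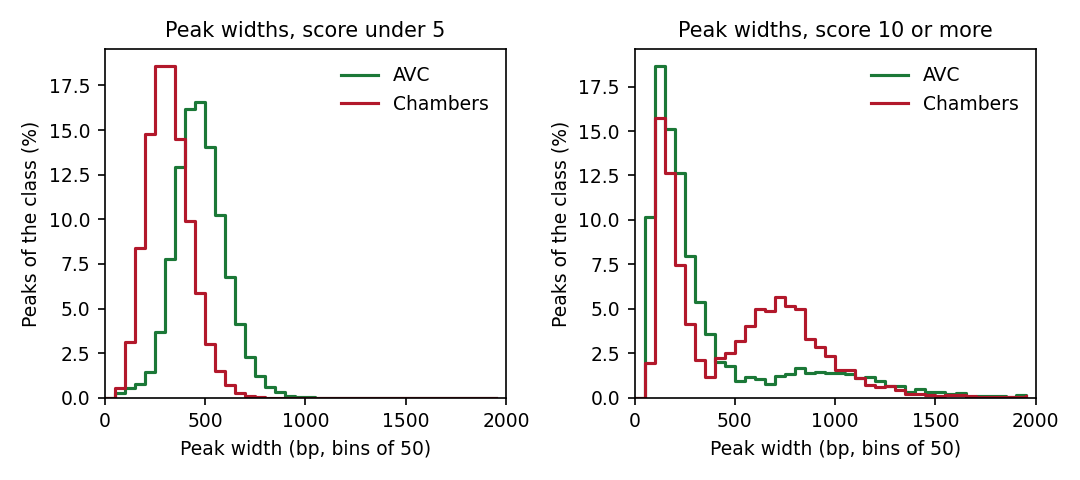
Distribution of peak widths in bins of 50 bp, as a percentage of the peaks of each class, for peaks with a score under 5 (left) and of 10 or more (right); lines are AVC (green) and chambers (red). Peaks with a score of 10 or more form a narrow group in both lists and a broad group that is larger in the chambers, 2166 peaks against 724.

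The 5 peaks of highest score in each list lay on chromosome 9, at loci called in both tissues. In AVC coordinates these were 3025289 to 3025701 (score 38.74), 35112742 to 35113191 (38.73), 3032328 to 3032516 (38.70), 2999992 to 3000298 (38.63) and 123370908 to 123371354 (38.59). The chamber scores of the overlapping peaks were 37.68, 37.69, 37.62, 37.53 and 37.57. Of these loci, 3 lay at the assembled start of the chromosome, next to the centromere. Scores are set within each chromosome, so these need not be the strongest peaks of the genome. Their signal values ran from 5814 to 64190 in the AVC and from 2270 to 35043 in the chambers. The highest values of the lists were 572185 and 257052.

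The peaks of highest score called in the chambers alone were broad. Because scores are set within each chromosome, their order across chromosomes is not an order of enrichment; of the 5 named in each list, 3 were also among the 5 of highest signal value. The first was on chromosome 5 at 122551309 to 122552960, with a score of 22.99 and a width of 1652 bp; an AVC peak lay within 1 kb of it. The other 4 had no AVC peak within 1 kb. They were on chromosome 2 at 10000864 to 10001748 (score 20.81), chromosome 4 at 45025620 to 45026574 (20.74), chromosome 14 at 17075951 to 17076996 (20.62) and chromosome 3 at 32294807 to 32295810 (20.49).

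The peaks of highest score called in the AVC alone were also broad, between 1325 and 1477 bp, and none had a chamber peak within 1 kb. They were on chromosome 7 at 59168891 to 59170265 (score 16.12), chromosome 8 at 46972175 to 46973594 (15.44), chromosome 9 at 77868843 to 77870229 (15.40), chromosome 7 at 104319753 to 104321229 (14.92) and chromosome 9 at 35148962 to 35150286 (14.10). In their own list they ranked between 1872 and 2215 by score, and the chamber-only peaks above ranked between 886 and 1240.

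AVC and chamber peaks were unevenly spread over regions of 100 kb. Among 1304 windows with at least 20 peaks, AVC peaks made up 50.2%, which was the baseline. In 80 windows the interval of the AVC share lay above it and in 47 below it. Binomial draws at the baseline gave 20.8 and 21.1 on average, and at most 32 and 36. These draws took peaks as independent, which neighbouring peaks of a window are not. They therefore do not show how much of the excess goes beyond such dependence. With peaks of at least 300 bp alone, the counts were 46 and 34 of 770 windows, and with scores of at least 3 they were 12 and 9 of 208. Against the AVC share of all peaks, 56.6%, in place of the baseline, they were 23 and 170, so the balance of directions depended on the baseline.

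**Figure D3:**
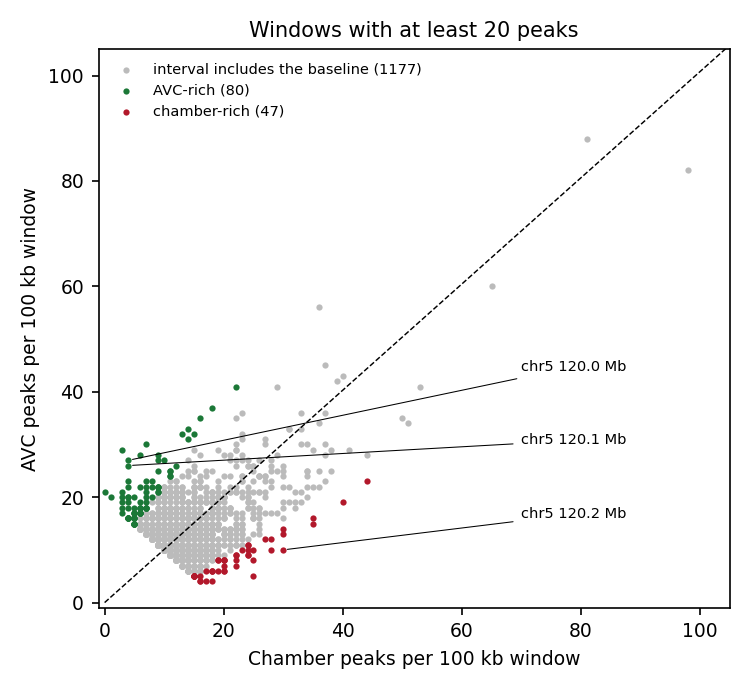
Number of AVC peaks against number of chamber peaks in each of the 1304 windows of 100 kb with at least 20 peaks; the dashed line is the baseline AVC share of 50.2%. Green points are the 80 AVC-rich windows, red points the 47 chamber-rich windows, grey points windows whose interval includes the baseline, and labels mark 3 adjoining windows on chromosome 5.

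AVC-rich windows lay on chromosomes 5, 7, 12, 13, 14 and 17 among the 10 named. Chromosome 13 held 2 adjoining pairs. From 12.9 to 13.0 Mb there were 29 AVC and 3 chamber peaks, and from 13.0 to 13.1 Mb 21 AVC peaks and no chamber peak, an AVC share of 100% (83.9 to 100). From 56.6 to 56.7 Mb there were 21 AVC and 3 chamber peaks, and from 56.7 to 56.8 Mb 23 and 4. On chromosome 5, 27 AVC and 4 chamber peaks lay between 120.0 and 120.1 Mb, a share of 87.1% (70.2 to 96.4), and 26 and 4 between 120.1 and 120.2 Mb, a share of 86.7% (69.3 to 96.2). The other named windows held 20 AVC peaks and 1 chamber peak on chromosome 14 from 20.7 Mb, 20 and 3 on chromosome 12 from 53.3 Mb, 28 and 6 on chromosome 17 from 40.1 Mb, and 22 and 4 on chromosome 7 from 124.6 Mb.

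Chamber-rich windows lay on chromosomes 1, 2, 5, 10, 11, 13 and 17 among the 10 named. Chromosome 11 held 25 chamber and 5 AVC peaks between 69.2 and 69.3 Mb, an AVC share of 16.7% (5.64 to 34.7), and 28 and 10 from 98.6 Mb. Chromosome 5 held 18 and 4 from 22.9 Mb and 30 and 10 from 120.2 to 120.3 Mb, where the AVC share was 25% (12.7 to 41.2) and 13 chamber peaks but 1 AVC peak had a score of 5 or more. Chromosome 2 held 17 and 4 from 84.5 Mb and 20 and 6 from 119.9 Mb. The others held 25 and 8 on chromosome 10 from 18.1 Mb, 22 and 7 on chromosome 13 from 23.8 Mb, 20 and 6 on chromosome 1 from 155.1 Mb, and 16 and 4 on chromosome 17 from 35.3 Mb.

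The chromosome 5 windows adjoined each other. The pair of AVC-rich windows, with 53 AVC and 8 chamber peaks, was followed directly by the chamber-rich 100 kb from 120.2 Mb. The windows outside them, from 119.9 and from 120.3 Mb, held 3 and 4 AVC peaks and 2 and 3 chamber peaks. By score the 53 AVC peaks had a median percentile of 61.9 among AVC peaks of the chromosome (bootstrap interval 46.3 to 69.8). Of the 53, 9 had a score of 5 or more. On this small count, that was a larger share than in the whole AVC list, 8716 of 87572 (9.95%). Among 372 pairs of adjoining windows this was the single pair with opposite directions. Shuffling the directions over the windows gave 1.81 such pairs on average, so the number of pairs did not exceed chance. The shuffle ignored how far each share lay from the baseline, so it does not judge the shares of this pair. Adjoining AVC-rich windows formed 8 pairs, against 1.15 on average and at most 5 after shuffling, and adjoining chamber-rich windows formed 1 pair, against 0.35.

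**Figure D4:**
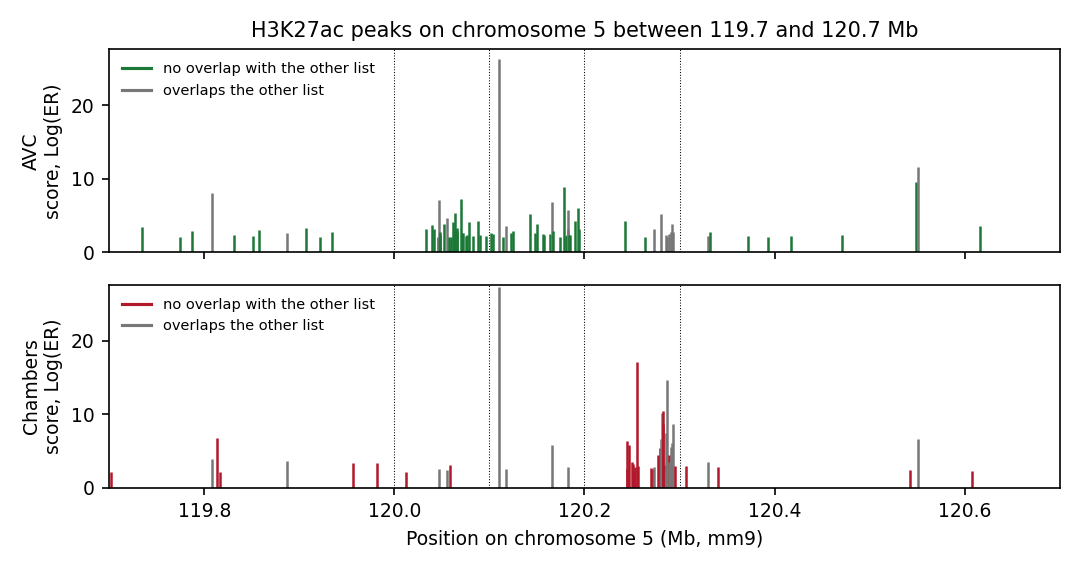
H3K27ac peaks on chromosome 5 between 119.7 and 120.7 Mb (mm9); each line is a peak at its midpoint, its height the caller's score, coloured where it overlaps no peak of the other list and grey where it does, with dotted lines at the window borders. AVC peaks cluster between 120.0 and 120.2 Mb, 53 against 8 in the chambers, and chamber peaks between 120.2 and 120.3 Mb, 30 against 10 in the AVC.

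Other regions were dense in both tissues. Between 119.8 and 119.9 Mb on chromosome 7 there were 60 AVC and 65 chamber peaks, a share of 48.0% (39.0 to 57.1). Windows on chromosome 16 from 24.4 Mb (41 and 53 peaks), chromosome 17 from 12.9 Mb (34 and 51) and chromosome 14 from 63.8 Mb (35 and 50) had intervals that included the baseline. The window on chromosome 11 from 3.0 Mb, at the assembled start of the chromosome, held 82 and 98.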

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

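Counts of peak classes stayed within 1.5 times except where the lists were shortened or the overlap loosened. With the stronger 50% of each list, 11743 AVC and 12196 chamber peaks were shared and 32043 and 21350 were not; ranking by signal value instead gave 11738, 12191, 32048 and 21355. Cutting the query list alone left 28844 AVC-only and 18333 chamber-only peaks. Counting neighbours within 1 kb gave 31895 shared chamber peaks. With peaks of at least 300 bp, 12693 AVC and 12948 chamber peaks were shared and 26373 were chamber-only. These shortened lists hold fewer peaks by construction. The chambers had the larger shared percentage under all 7 alternatives. Except with equal peak numbers, the AVC list stayed the longer one, which by itself lowers its percentage, so those settings add little. With equal peak numbers the gap narrowed to 26.97% (AVC) against 28.46%. The 300 bp limit and the ranking by signal value were chosen after seeing the data. Strong broad peaks numbered 5163 (AVC) and 5844 (chambers) at a score of 5; among the 5000 highest signal values the AVC had 2088 and the chambers 2627. From 80 and 47 of 1304 windows, AVC-rich windows fell to 12 and chamber-rich windows to 9 of 208 at scores of at least 3. AVC-rich windows fell to 46 of 770 at 300 bp. These counts fell along with the number of windows reaching 20 peaks. With the baseline over all peaks, 56.6%, the counts were 23 and 170. Of the 20 named AVC-rich and chamber-rich windows, 17 still held 20 peaks with equal peak numbers, 15 at 300 bp and 2 at scores of at least 3. The opposite pair on chromosome 5 was kept with shifted windows, equal peak numbers, 300 bp peaks and the other baseline. It was not kept with 50 kb windows. There the first 50 kb from 120.2 Mb held fewer peaks than the minimum of 10, so no adjoining pair could form at that border. Nor was it kept at scores of at least 3. There the AVC-rich window held 11 AVC and 2 chamber peaks (84.6%), under the minimum of 20, and the chamber-rich one 4 and 20 (16.7%). The promoter, gene list and motif analyses and their alternatives were not run, for want of mm9 references here. No paired analysis was possible because each group has 1 sample. The unknown depth, with no input library used here, limits what a missing peak shows.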

Other observations

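The tests of signal values at strong loci chosen on a single list, gene density, the value ratios of narrow peaks and the chromosome 5 region below were chosen after their patterns had been seen; the comparisons of values at loci broad or narrow in both lists and of peak borders were set before their values were seen.

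The 2 libraries also differed along chromosomes. Peaks were called and scored chromosome by chromosome, so the score threshold need not be the same signal cut on each. With 1 library per tissue, the counts below cannot be put down to tissue. The X chromosome held 609 AVC peaks, 0.695% of the list (0.641 to 0.753), and 933 chamber peaks, 1.39% (1.303 to 1.482), although the AVC list was longer. Both X densities, 3.66 (AVC) and 5.61 (chambers) peaks per Mb, lay far below those of the autosomes, the lowest of which were 28.5 and 22.2. Among autosomes the ratio of AVC to chamber peaks ran from 1.02 on chromosome 19 and 1.03 on chromosome 11 to 1.60 on chromosome 12 and 1.65 on chromosome 14. The mitochondrial genome, which carries no histones, held 6 peaks in each list, covering 15871 bp (AVC) and 15898 bp (chambers) of its 16299 bp.

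The AVC list was longer but had fewer strong broad peaks. A depth difference alone would scale strong broad and strong narrow loci alike if the signal value did not depend on the called width. For this unnamed value that is unknown. The comparison set beforehand, at loci broad or narrow in both lists, gave a quotient of the broad (0.781) and the narrow (1.65) median AVC-to-chamber value ratio of 0.474 (95% bootstrap interval 0.462 to 0.487). It decides nothing, because each library sets the widths: 39.9% of AVC peaks and 5.60% of chamber peaks with a score under 5 are at least 500 bp wide, so that being broad in both lists selects unusual chamber peaks. Strong loci were then chosen on a single list, with the highest overlapping value of the other list as partner; a peak without a partner took an extreme ratio, high on the AVC list and 0 on the chamber list. This choice pushes the quotient up on the AVC list and down on the chamber list, so a value in that direction decides nothing either. Such a value was 0.287 (0.275 to 0.299, chromosomes resampled) over strong chamber peaks, where 316 broad peaks had no partner. At scores of 5 or more, with peaks resampled singly, the values were 1.22 (1.17 to 1.25) on the AVC list and 0.291 (0.284 to 0.299) on the chamber list. There, 2001 broad AVC peaks and 1960 broad chamber peaks had no partner. Against the push went 0.946 (0.861 to 0.988) over strong AVC peaks, 57 broad ones without a partner, and 0.920 (0.791 to 0.986, peaks resampled singly) over loci with a single partner. Leaving out only loci whose chamber partner spans several AVC peaks, it was 1.01 (0.956 to 1.06). A difference in depth alone and weaker enrichment over background in the AVC library therefore cannot be told apart, and both stay open. Background spread evenly over the genome would leave AVC-only peaks unrelated to gene density. Across 19 autosomes their Spearman rho with protein-coding genes per Mb was -0.25 (-0.47 to -0.18 leaving out each chromosome). Pearson was 0.07, and -0.36 without chromosomes 7 and 11. For chamber-only peaks rho was 0.52 (0.44 to 0.61), and Pearson 0.56, or 0.55 without them. Chromosomes are not replicates. The X chromosome, left out there, held 2.05 AVC-only peaks per Mb, against 21.9 to 34.5 on the autosomes. This goes against an even spread over all chromosomes, unless the threshold on X was a higher signal cut. Chamber peaks were sparse on X too. The 80 AVC-rich windows exceeded the at most 32 in draws, but those draws took peaks as independent and did not model even background. Weaker acetylation at broad loci in AVC cells, or a more mixed cell population, remains open and untested.

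Strong narrow peaks were shared almost without exception, 2054 of 2057 in the AVC. Reads piling up at fixed places, such as collapsed repeats, in any library are a candidate explanation. The border criterion, set first, was not met: the borders of 1521 narrow pairs did not match better than those of 175 strong broad pairs, with a median Jaccard index of 0.726 (0.708 to 0.741) against 0.810 (0.779 to 0.842), although an equal shift of the borders lowers this index more in short peaks, and the median border shift was 52 bp in narrow and 191 bp in broad pairs. A comparison of value ratios, added after that, showed AVC-to-chamber ratios with an interquartile range of 0.22 on the log2 scale (0.21 to 0.23). For the broad pairs it was 0.77 (0.69 to 0.94), the direction a fixed source would give. Narrow and broad pairs were not matched on signal value, on which counting error depends, so this range does not single out a fixed source. In both lists the Mb-sized bin with the most strong narrow peaks was the one from 3 Mb on chromosome 9. It held 79 of the 2057 AVC and 65 of the 1819 chamber peaks, so most lay elsewhere. Without an input library used here, repeats cannot be told apart from true narrow acetylation.

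The adjoining AVC-rich and chamber-rich windows on chromosome 5 were the 1 opposite pair among 372 adjoining pairs of 100 kb windows. That number was no more than the 1.81 that shuffled directions gave on average. The shuffle counted directions only and did not weigh how extreme these windows were. Raised background limited to the AVC-rich windows stays open: their 53 AVC peaks had a median score percentile on the chromosome of 61.9, with an interval of 46.3 to 69.8 that includes 50, while the 30 chamber peaks of the next window had 79.2 (56.2 to 86.9). These percentiles rank called peaks only, so 50 is not the level of background and the comparison cannot decide. A tissue difference, which the design names, stays open as well, since 1 library per tissue cannot separate tissue from library.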
